A study of Mus musculus with 4 samples.

How the data were processed

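Poly(A) RNA from adult mouse kidney, collected at 60 days of age, was sequenced in 4 libraries. Per the labels, 2 libraries came from wild-type mice (WT) and 2 from mice heterozygous for a LacZ allele of Tshz3 (HET). Each library was made from a pool of RNA, and the labels speak of 3 kidneys per group. They do not say whether both pools of a genotype hold different kidneys, so the p-values measure only the spread between pools, part of which may be technical. The 4 Y-linked genes differed by a median of -1.92 (log2) from HET replicate 2 to 1, and Xist by 1.11 from WT replicate 1 to 2. These steps argue against the same kidneys in equal shares in both pools of a genotype. The sex of the mice, the strain and the structure of the LacZ allele are not given in the sources used here.

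The authors deposited a table of TPM, a share of transcripts corrected for gene length and depth, for 54232 genes, with the coordinates and summed length of their exons, and a table of their own comparison. The TPM of each library sum to 1000000. For 97 genes the authors' deposited table gives a mean normalized count, a log2 fold change with its standard error, a p-value and an adjusted p-value. It also holds a score per gene, which per the file headers is the test statistic and equals the log2 fold change divided by its standard error. Per the submitters' processing notes, the genome build was mm10 and DESeq, DESeq2 and edgeR were among the tools, with no versions. The aligner, the read counter, the library kit and its strand setting are not given in the sources used here. Per the file headers the values came from alignments marked unique, with no more detail. Reads of overlapping genes cannot be told apart.

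TPM multiplied by exon length came out as whole multiples of a smallest step, taken as 1 read, for 100% of the values above 0, within a tolerance of 0.001 reads. The largest deviation was 9e-09 reads. The recovered reads summed to between 62631750 and 70792042 per library. Scaled by median-of-ratios factors, they matched the mean normalized counts of the authors' deposited table to a relative difference of 5e-15. The recovered reads were used for depth, scaling, filtering and limma-voom only. Both libraries of a genotype differed far beyond counting error, with a chi-square per degree of freedom of 70.6 for WT and 73.2 for HET, so no library was a copy of another.

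The design fixed before the data were examined assumed counts. As the deposited unit is TPM, the test used was limma 3.58.1 in R 4.3.3 on log2(TPM + 0.5), with a variance trend and robust moderation (statmod 1.5.0). Genes were called at a Benjamini-Hochberg adjusted p below 0.1. A fold change is thus on the log2(TPM + 0.5) scale, which understates the change of genes at low levels. TPM were scaled between libraries with trimmed mean of M values (TMM) factors of the recovered reads, 0.901 and 0.989 for WT replicates 1 and 2 and 1.05 and 1.07 for HET replicates 1 and 2. Levels are given as scaled TPM, with the SD over n = 2 pools. Genes were tested if they had at least 10 reads, at the median depth, in 2 libraries and at least 15 reads in all, which left 22356 genes. An exact permutation test of 1 gene, 2 libraries against 2, cannot give a two-sided p below 0.333. Single-gene tests therefore rest on the variance shared across genes. Gene classes came from GENCODE M21, which holds 54165 of the identifiers, 52910 with the same start and end.

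The fit was tested on simulated reads with the means and depths of these libraries and a median dispersion of 0.0172. In the simulated HET vs WT comparison 22156 genes were tested and 200 were changed. The fit called 12 of 50 genes changed 2-fold, 40 of 50 changed 4-fold, 48 of 50 changed 8-fold and 48 of 50 changed 16-fold. It also called 17 unchanged genes, 10.3% of its 165 calls. With no gene changed it called 0 genes and 0 lists, and a list shifted on purpose was called with 0 other lists. The simulated genes varied independently of each other, so this does not test list calls where the members of a list move together.

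Gene lists for 38 cell types, pathways and other groups were fixed before the data were examined, and 733 of their entries were tested. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, and as alternatives with an estimated correlation and with fry, adjusted over the lists. The genes named in the text followed a rule fixed at the same time. It took Tshz3 and its paralogs, 8 kidney genes, the 12 called genes with the largest change per direction, up to 4 called members per list, the 5 largest changes per direction in the authors' deposited table and the 3 smallest p per direction. Clone names and pseudogenes were left out except among the smallest p, and called genes needed at least 1 read per 1000000. Other list members, sex-linked genes and neighbours of Tshz3 were named after their values were seen. Results for some genes are not reported here. Genes of the authors' deposited table were counted in the lists and around Tshz3 by Fisher's exact test (two-sided), against the 17591 tested genes whose mean normalized count reached the lowest in that table.

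Alternatives fixed in advance were other scaling factors, other filters, the replicate number as a block, leaving out each library, limma-voom on the recovered reads, stricter thresholds, other list tests, other windows and leaving out the genes of other cell types, sex and neighbours of Tshz3. TPM without scaling, pseudocounts of 0.1 and 1, moderation without the robust option, covariates for sex-linked transcripts, limma-voom for the lists and the Fisher tests on the authors' genes were added after the data had been seen. Xist differed by 1.11 (log2) between the WT pools but by 0.068 between the HET pools, so its slope rested almost wholly on the WT pools. The Y-linked genes differed by a median of -1.92 from HET replicate 2 to 1, against -0.51 from WT replicate 1 to 2. With 4 libraries neither covariate can separate sex from genotype or from single pools. Figures were drawn with matplotlib 3.10.9.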

Results

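RNA sequencing was used to compare adult kidneys of wild-type mice with those of mice heterozygous for a LacZ allele of Tshz3, which encodes a zinc-finger transcription factor of the teashirt family. There were 2 libraries of pooled RNA per genotype, from kidneys collected at 60 days of age. Recovered reads numbered 70319173 and 70717617 in WT replicates 1 and 2, and 62631750 and 70792042 in HET replicates 1 and 2. Between 30426 and 32800 genes had a read in a library. The series concerns kidney dysfunction in the heterozygotes, and the comparison asks which kidney transcripts differ between the genotypes.

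Tshz3 was not lower in the libraries labelled HET. The gene (ENSMUSG00000021217, chromosome 7, 36698118 to 36773553, mm10) was at 0.653 and 0.723 TPM in the WT libraries and 0.833 and 0.760 TPM in the libraries labelled HET. These levels rested on 104, 127, 137 and 145 reads. The log2 fold change was 0.13 ± 0.17 (SE), with a 95% confidence interval from -0.29 to 0.54 (limma adjusted p = 0.790). A halved level would be -0.49 on this scale, outside the interval. The log2 fold change of Tshz3 was 0.28 without scaling of the TPM, 0.20 with limma-voom, and 0.076 and 0.035 with Y-linked gene and Xist level as covariates. The value sums all exons of the gene and so may include exons kept in the LacZ allele, whose structure is not given, and 5 other annotated genes overlap Tshz3. The level thus did not bear out the labels, and all directions below are those of the libraries as labelled. The paralogs did not pass the test. Tshz1 (chromosome 18) was at 20.9 ± 3.13 TPM in WT and 18.1 ± 0.0898 TPM in the libraries labelled HET (SD, n = 2; limma adjusted p = 0.659), a log2 fold change of -0.19 that was 0.059 without scaling of the TPM, -0.039 without WT replicate 1 and -0.35 without WT replicate 2. Tshz2 (chromosome 2) was at 8.76 ± 1.504 TPM and 9.71 ± 0.416 TPM (SD, n = 2; limma adjusted p = 0.731), and its log2 fold change of 0.15 changed sign without WT replicate 1 (-0.015) and was 0.30 without WT replicate 2.

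Npy and the pseudogene Gm8420 passed the test. Npy, which encodes the sympathetic transmitter neuropeptide Y (chromosome 6, 49822710 to 49829507), fell from 22.3 ± 5.70 TPM in WT to 2.37 ± 0.364 TPM in the libraries labelled HET (SD, n = 2). The WT mean was 9.42 times the HET mean, and the log2 fold change was -2.97 ± 0.21 (SE; limma adjusted p = 0.0560). Gm8420, a processed pseudogene (chromosome 1, 51940664 to 51941261), rose from 0.273 ± 0.0190 TPM to 10.2 ± 2.10 TPM (SD, n = 2), with a log2 fold change of 3.78 ± 0.21 (SE; limma adjusted p = 0.0203). Processed pseudogenes can share reads with the gene they were copied from, so the origin of these reads is uncertain. In all, 2 of 22356 genes were called, 1 in each direction. At an unadjusted p under 0.05 there were 1624 genes, 851 higher and 773 lower, where chance gives 1118. Without WT replicate 1 there were 591 of 23603 tested, fewer than chance gives, and with Xist level as a covariate 402, while without scaling of the TPM there were 2760. Both HET libraries lay above both WT libraries for 4882 genes and below for 5171, together 45.0% of the genes, where chance gives 33.3%. Without WT replicate 1 the called genes were Gm8420 and Iglj1, and Npy was not called (limma adjusted p = 0.140). Without another library the count was 7 (WT replicate 2), 76 (HET replicate 1) or 53 (HET replicate 2). Neither gene was called by limma-voom (adjusted p = 0.162 for both), which called 0 genes with 1771 at an unadjusted p under 0.05. They were not called without a filter on low genes (0.721 and 0.606) or with Xist level as a covariate (0.621 and 0.618) either, and Npy was not called by limma without robust moderation (0.213).

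**Figure D1:**
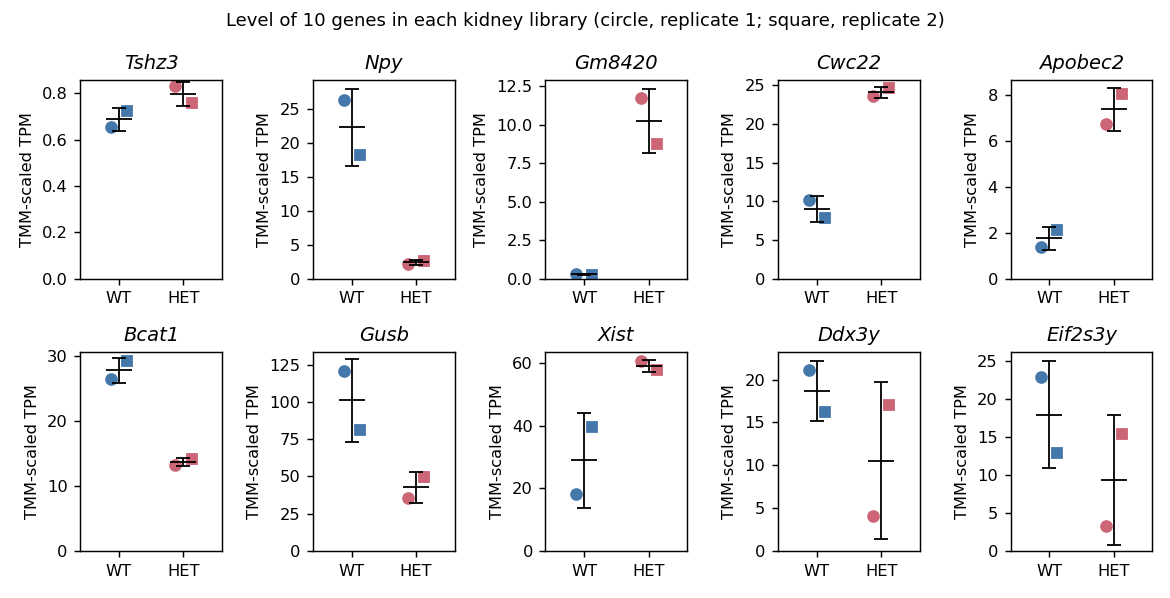
Level of 10 genes in each library as TMM-scaled TPM (y axis), with circles for replicate 1, squares for replicate 2, and the mean and SD of each genotype as labelled. Npy was at 2.11 and 2.63 TPM in the HET libraries against 26.3 and 18.3 TPM in WT, and Ddx3y was at 4.02 TPM in HET replicate 1 against 17.0 TPM in HET replicate 2.

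Other genes with small p did not pass the adjustment over all genes. Gm14094, a processed pseudogene on chromosome 2, was at 0.105 ± 0.0683 TPM in WT and 2.30 ± 0.598 TPM in the libraries labelled HET (SD, n = 2; limma adjusted p = 0.303). Cwc22, a splicing factor gene on chromosome 2 (77881159 to 77946375), was at 8.98 ± 1.67 TPM and 24.1 ± 0.739 TPM (SD, n = 2; limma adjusted p = 0.385). Gm13727 overlaps the end of Cwc22 on the same strand, so that their reads may be shared, and was at 3.54 ± 1.17 TPM and 14.6 ± 0.508 TPM (SD, n = 2). Bcat1, which encodes the cytosolic branched-chain aminotransferase, was at 27.8 ± 1.97 TPM in WT and 13.7 ± 0.623 TPM in HET (SD, n = 2; limma adjusted p = 0.560). The pseudogene Rpl17-ps5 had a log2 fold change of -1.14 ± 0.16 (SE). With only genes of at least 1 read per 1000000 in 2 libraries tested, Apobec2, Cwc22 and Gm13727 were called as well (limma adjusted p = 0.0887 for each). Without HET replicate 1, limma called Cwc22 (0.0969), Gm14094 (0.0322) and Apobec2 (0.0900), and without HET replicate 2 Cwc22 (0.0943) and Gm14094 (0.0185).

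The authors' deposited table lists 97 genes, 55 higher and 42 lower in HET, with adjusted p up to 0.0997. In the authors' deposited table the largest increases among genes with a usual symbol were those of Apobec2 (log2 fold change 1.27, adjusted p = 1.05e-05), Cwc22 (1.18), Ciita (1.10), Rasl10b (1.06) and Col11a2 (1.00). Ciita encodes the master transactivator of MHC class II genes, and Col11a2 a fibrillar collagen chain. The largest decreases in the authors' deposited table were those of Npy (-1.99, adjusted p = 8.10e-17), Gusb (-0.96), Ucp1 (-0.94), Bcat1 (-0.92) and Synpr (-0.90). The authors' fold changes are not on the scale used here. Of the genes just named, only Ciita and Col11a2 changed more there than in the limma fit. Gm8420 is listed by the authors at 4.19-fold, while the ratio of its mean TPM here was 37.4. Gusb encodes the lysosomal enzyme beta-glucuronidase, Ucp1 the uncoupling protein of brown fat and Synpr the synaptic vesicle protein synaptoporin. Here Apobec2 was at 1.75 ± 0.522 TPM in WT and 7.39 ± 0.932 TPM in HET, Ciita at 0.773 ± 0.101 TPM and 2.10 ± 0.268 TPM, and Ucp1 at 26.2 ± 12.01 TPM and 9.91 ± 1.71 TPM (SD, n = 2). All 97 genes had the same sign in the limma fit, 96 had an unadjusted p under 0.05 and 2 were called. Rasl10b and Synpr were called by limma without HET replicate 2 (0.0731 and 0.0801). Across these genes, which are not independent replicates, the Spearman correlation of both sets of log2 fold changes was 0.945. Both sets come from the same 4 libraries, and the genes were chosen by their change there. Like signs, small p and a high correlation were thus built in.

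**Figure D2:**
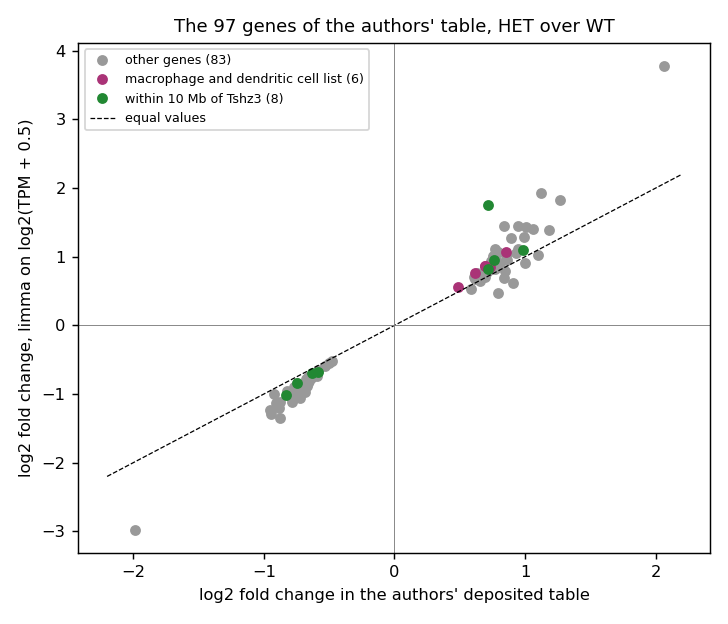
Log2 fold change, HET over WT as labelled, of the 97 genes in the authors' deposited table (x axis) against the limma estimate on log2(TPM + 0.5) (y axis), one point per gene, with equal values on the dashed line. All 97 genes have the same sign on both axes, which use the same libraries but estimate fold changes in different ways.

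Genes known to be higher in male than in female mouse kidney were lower in the libraries labelled HET, and the pools differed in sex-linked transcripts. Of 20 members 19 were lower, with a median log2 fold change of -1.10 (camera adjusted p = 2.16e-07). With an estimated correlation the adjusted p = 0.806. Over all genes 0 members were called, and 1, Gusb, when adjusted over the list alone. Relative to the WT mean the list's median was 0.35 and -0.35 in WT replicates 1 and 2, and -1.58 and -0.40 in HET replicates 1 and 2. Gusb was at 121 and 81.4 TPM in the WT libraries and 35.4 and 49.8 TPM in the HET libraries, and Cyp7b1, an oxysterol hydroxylase gene, at 169.7 and 117 TPM and 25.5 and 81.8 TPM. Xist, transcribed from the inactive X chromosome, was at 18.1 and 39.7 TPM in WT and 60.5 and 57.7 TPM in HET. The Y-linked gene Ddx3y was at 21.1 and 16.2 TPM in WT and 4.02 and 17.0 TPM in HET, and Eif2s3y at 23.0 and 13.0 TPM and 3.27 and 15.4 TPM. None of these sex-linked genes passed the test (limma adjusted p = 0.622 for Xist and 0.664 for Ddx3y). With Xist level as a covariate the male list was not called (camera adjusted p = 0.329, median -0.17). With the Y-linked genes as a covariate it was still called lower (camera adjusted p = 0.000167, median -0.33). The median log2 fold change was -0.62 without WT replicate 1 and -0.40 without HET replicate 1.

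Genes of macrophages and dendritic cells were higher in the libraries labelled HET. Of 18 members 17 were higher, 13 of them in both HET libraries relative to both WT libraries, where chance gives 16.7% in that direction and 21.8% of all tested genes were. The median log2 fold change was 0.55 (camera adjusted p = 1.22e-10), and the adjusted p = 0.806 with an estimated correlation. Over all genes 0 members were called, and 13 when adjusted over the list alone. Lyz2, which encodes lysozyme, was at 38.7 ± 9.15 TPM in WT and 80.7 ± 4.601 TPM in HET, and Ctss, which encodes cathepsin S, at 18.0 ± 1.11 TPM and 33.0 ± 0.455 TPM (SD, n = 2). The MHC class II gene H2-Aa was at 69.0 ± 0.497 TPM and 102 ± 2.79 TPM, and Adgre1, which encodes the macrophage marker F4/80, at 2.57 ± 0.702 TPM and 5.02 ± 0.447 TPM (SD, n = 2). Csf1r, the receptor gene for colony-stimulating factor 1, was at 37.1 ± 4.89 TPM in WT and 35.9 ± 5.58 TPM in HET (SD, n = 2). The authors' deposited table holds 6 members (Lyz2, Ctss, Adgre1, Cd74, H2-Aa and H2-Ab1), all higher in HET, where 0.0993 would be there by chance (Fisher's exact test, two-sided, adjusted p = 1.61e-08 over 38 lists). H2-Aa and H2-Ab1 lie close together on chromosome 17 (34263209 to 34287827), near Col11a2 of that table, so they may not be separate signals. Fisher's test takes genes as independent, but members of this list moved together (estimated correlation 0.30). It also rests on the same libraries as camera, so it is not separate support. No other list passed that test. With Xist level as a covariate the median of macrophage and dendritic cell genes was 0.35 (camera adjusted p = 5.27e-05). Its slope rested almost wholly on the WT pools, so this is no control for sex. The lymphocyte list did not move alongside in both libraries: its median relative to the WT mean was -0.15 in HET replicate 1 and 1.27 in HET replicate 2.

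Interferon response genes were higher as well, all 23 of 23 members, 19 of them in both HET libraries relative to both WT libraries. The median log2 fold change was 0.43 (camera adjusted p = 1.09e-08), and the adjusted p = 0.806 with an estimated correlation. Over all genes 0 members were called, and 9 when adjusted over the list alone. Iigp1, which encodes an interferon-inducible GTPase, was at 6.38 ± 1.31 TPM in WT and 13.5 ± 1.54 TPM in HET (SD, n = 2). With Xist level as a covariate the list's median was 0.20 (camera adjusted p = 0.0189), and without scaling of the TPM it was 0.66. Iigp1 and Oas2 are higher in the authors' deposited table (0.85 and 0.79).

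In all, camera called 20 of 38 lists, 15 higher and 5 lower in the libraries labelled HET. With an estimated correlation 0 lists were called, and those 20 all had an adjusted p = 0.806. With fry 0 were called (lowest adjusted p = 0.603). Both other ways of parting the 4 libraries 2 against 2, which mix the genotypes, gave 16 and 23 called lists. Cell cycle genes were higher (20 of 21 members, median 0.44, camera adjusted p = 2.98e-06), with the proliferation marker Mki67 at 1.08 ± 0.512 TPM in WT and 2.12 ± 0.458 TPM in HET (SD, n = 2). Interstitial fibroblast and matrix genes were higher too (22 of 22, median 0.39, camera adjusted p = 2.41e-05), with the fibronectin gene Fn1 at 19.3 ± 7.15 TPM and 31.3 ± 0.977 TPM (SD, n = 2). Of these members, 14 cell cycle genes and 10 fibroblast and matrix genes were above both WT libraries in both HET libraries. Both lists had an adjusted p = 0.806 with an estimated correlation, and 0 members called over all genes or adjusted over the list alone. With Xist level as a covariate camera called fibroblast and matrix genes lower (0.0711, median -0.22). Camera did not call cell cycle genes (0.915, median 0.024, tested as lower) with Xist level as a covariate. Among lists still called, the median was 0.63 for fibroblast and matrix without scaling of the TPM. Median log2 fold changes were 0.23 (cell cycle genes) and 0.072 (fibroblast and matrix) without WT replicate 1, 0.68 (cell cycle genes) without WT replicate 2 and 0.26 (fibroblast and matrix) without HET replicate 2.

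Lists for tubular injury, podocytes and the distal nephron were higher, and were not called without HET replicate 1. The tubular injury list (20 of 24 members higher, median 0.44) had a camera adjusted p of 0.00151, and 0.349 without that library. The kidney injury marker Havcr1 was at 17.1 and 22.8 TPM in WT and 58.2 and 24.1 TPM in the libraries labelled HET, and Lcn2, which encodes a lipocalin released by injured tubules, at 1.37 and 1.72 TPM and 6.57 and 2.19 TPM. Neither passed the test (limma adjusted p = 0.623 and 0.622), though both did without HET replicate 2 (0.0801 and 0.0775). Vcam1, 1 member called when adjusted over the list alone, was at 3.10 ± 0.380 TPM in WT and 5.86 ± 0.134 TPM in HET (SD, n = 2), and is higher in the authors' deposited table (0.77). The camera adjusted p was 0.00237 for podocytes (20 of 22 higher, median 0.21), and 0.428 without HET replicate 1. For the distal convoluted and connecting tubule (13 of 15, median 0.35) it was 0.00237, and 0.933 in the other direction without HET replicate 1. Calb1, the calbindin gene of that segment, was at 83.8 and 89.7 TPM in WT and 237 and 94.1 TPM in HET. Intercalated cells (13 of 16, median 0.20) went from 0.0205 to 0.732, collecting duct principal cells (14 of 16, median 0.28) from 0.0506 to 0.595 and the thick ascending limb (12 of 14, median 0.21) from 0.0534 to 0.290, each with a changed direction. In the distal tubule, intercalated cell and collecting duct lists the medians then stayed above 0 (0.0034, 0.0015 and 0.0013), unlike the direction of the test. The collecting duct and thick ascending limb lists were not called without WT replicate 1 either (0.363 and 0.128). Immediate early and stress genes (19 of 23, median 0.26) went from 0.00395 to 0.438. For each of these lists the adjusted p = 0.806 with an estimated correlation, and except for Vcam1 0 members were called over all genes or adjusted over the list alone. Without a filter on low genes camera did not call collecting duct (0.111, median 0.28) or thick ascending limb (0.101, median 0.21). With Y-linked gene level as a covariate camera did not call tubular injury (0.135, median 0.12), podocytes (0.351, median 0.061), distal tubule (0.873, median 0.0074), immediate early genes (0.363, median 0.11), intercalated cells (0.892, median -0.0011, tested as lower), collecting duct (0.603, median 0.0025, tested as lower) or thick ascending limb (0.327, median -0.095, tested as lower). Camera did not call tubular injury (0.121, median 0.19), podocytes (0.714, median 0.038), distal tubule (0.329, median 0.15), immediate early genes (0.714, median 0.066), intercalated cells (0.565, median 0.057), collecting duct (0.691, median 0.022, tested as lower) or thick ascending limb (0.703, median 0.021) with Xist level as a covariate. Among lists still called, the median was 0.44 for podocytes, 0.60 for distal tubule, 0.45 for immediate early genes, 0.44 for intercalated cells, 0.53 for collecting duct and 0.40 for thick ascending limb without scaling of the TPM. Median log2 fold changes were 0.16 (immediate early genes), 0.13 (intercalated cells), 0.16 (collecting duct) and 0.14 (thick ascending limb) without WT replicate 1, 0.32 (podocytes) without WT replicate 2, 0.17 (tubular injury), 0.11 (podocytes), 0.0034 (distal tubule), 0.090 (immediate early genes), 0.0015 (intercalated cells), 0.0013 (collecting duct) and -0.10 (thick ascending limb) without HET replicate 1 and 0.35 (podocytes), 0.66 (distal tubule), 0.39 (immediate early genes), 0.39 (intercalated cells), 0.52 (collecting duct) and 0.45 (thick ascending limb) without HET replicate 2.

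Of the kidney genes named in advance, none passed the test (limma adjusted p from 0.622 to 0.984). The sodium-chloride cotransporter gene Slc12a3 was at 49.98 ± 6.14 TPM in WT and 76.4 ± 9.41 TPM in the libraries labelled HET, and the renin gene Ren1 at 82.2 ± 7.08 TPM and 121 ± 36.2 TPM (SD, n = 2; limma adjusted p = 0.622 for both). Umod, which encodes uromodulin, was at 1992 ± 189.8 TPM and 2365 ± 516 TPM, and Slc12a1, the loop diuretic target, at 322 ± 23.4 TPM and 375 ± 42.4 TPM (SD, n = 2). The nephrin gene Nphs1 was at 10.95 ± 0.869 TPM and 13.5 ± 3.21 TPM, and the water channel gene Aqp2 at 337 ± 19.3 TPM and 355 ± 137 TPM (SD, n = 2). The log2 fold changes were 0.61 (Slc12a3), 0.52 (Ren1), 0.23 (Umod), 0.22 (Slc12a1), 0.28 (Nphs1) and 0.020 (Aqp2). They were 0.14 (Umod) and -0.037 (Aqp2) without WT replicate 1, 0.065 (Aqp2) without WT replicate 2, 0.21 (Ren1), 0.0093 (Umod), 0.10 (Slc12a1), 0.043 (Nphs1) and -0.38 (Aqp2) without HET replicate 1, and 0.83 (Ren1), 0.46 (Umod), 0.33 (Slc12a1), 0.51 (Nphs1) and 0.42 (Aqp2) without HET replicate 2. Over all alternatives they ranged from 0.34 to 0.86 for Slc12a3, 0.21 to 0.83 for Ren1, -0.00239 to 0.49 for Umod, 0.053 to 0.47 for Slc12a1, 0.037 to 0.52 for Nphs1 and -0.38 to 0.42 for Aqp2.

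**Figure D3:**
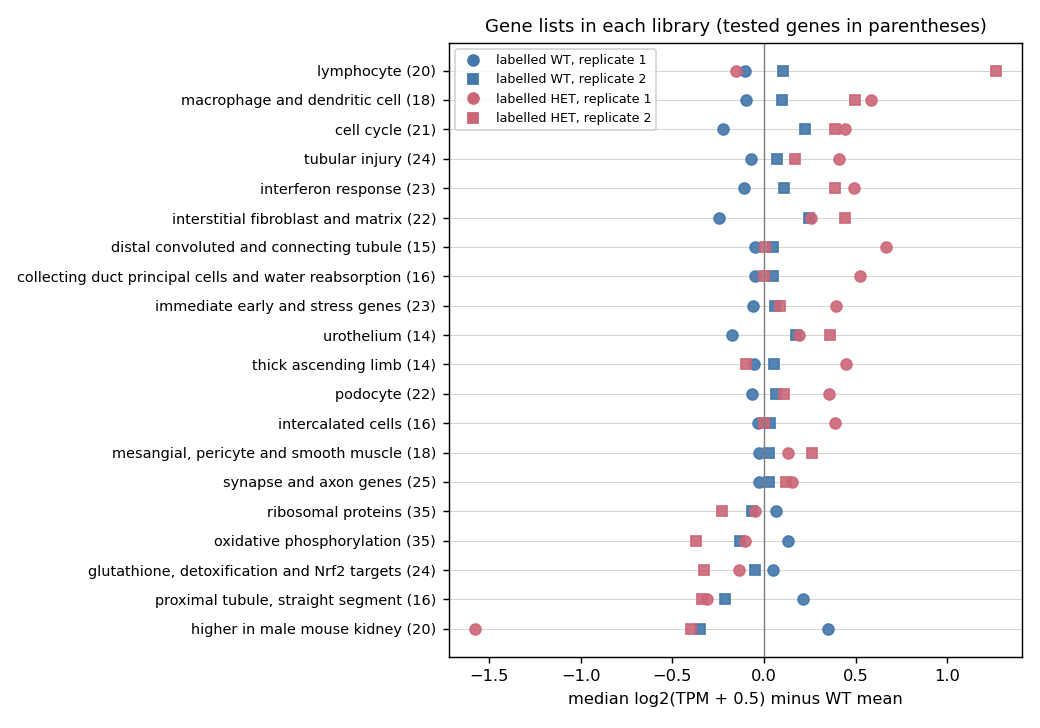
Median over the genes of each called list of log2(TPM + 0.5) minus the mean of the WT libraries (x axis), one point per library, with circles for replicate 1 and squares for replicate 2 of each genotype as labelled. The macrophage and dendritic cell list was at 0.585 and 0.497 in the HET libraries, and the male kidney list at -1.58 and -0.397.

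Oxidative phosphorylation genes were lower relative to other genes. All 35 members had a lower mean in the libraries labelled HET, with a median log2 fold change of -0.24 (camera adjusted p = 3.33e-06). Only 15 of them were below both WT libraries in both HET libraries. Relative to the WT mean the list's median was 0.13 and -0.13 in WT replicates 1 and 2, and -0.10 and -0.37 in HET replicates 1 and 2. HET replicate 1 was thus not below WT replicate 2. Ndufa4, which encodes a respiratory chain subunit, was at 684 ± 134 TPM in WT and 519.7 ± 44.2 TPM in HET (SD, n = 2). Genes of glutathione, detoxification and Nrf2 targets (20 of 24, median -0.26, camera adjusted p = 0.00720), ribosomal proteins (27 of 35, -0.17, 0.0102) and the straight proximal tubule (10 of 16, -0.28, 0.0493) were called lower too. For all of these lists the adjusted p = 0.806 with an estimated correlation, and 0 members were called over all genes or adjusted over the list alone. The straight proximal tubule list shares Cyp7b1 and Slc7a13 with the male kidney list and Slc3a1 and Aadat with the female kidney list, so it is not independent of them. Without HET replicate 2 the glutathione (0.806), ribosomal (0.183) and straight proximal tubule (0.284) lists were not called by camera, nor were the latter pair without WT replicate 1 (0.115 and 0.147). Without scaling of the TPM the median of all genes was 0.20 higher in HET, and the list medians were 0.015 for oxidative phosphorylation, 0.088 for ribosomal proteins, -0.0087 for glutathione and -0.024 for the straight proximal tubule, so the directions of oxidative phosphorylation and ribosomal proteins hold only relative to other genes. Camera then still called oxidative phosphorylation (6.48e-05), glutathione (0.00113) and the straight proximal tubule (0.00113) lower, but not ribosomal proteins (0.169). Camera did not call oxidative phosphorylation (0.869, median -0.023), glutathione (0.565, median -0.11), ribosomal proteins (0.714, median -0.055) or straight proximal tubule (0.869, median -0.013) with Xist level as a covariate. Median log2 fold changes were -0.12 (oxidative phosphorylation), -0.14 (glutathione) and -0.089 (straight proximal tubule) without WT replicate 1, -0.40 (oxidative phosphorylation) and -0.49 (straight proximal tubule) without WT replicate 2, -0.37 (oxidative phosphorylation) without HET replicate 1 and -0.10 (oxidative phosphorylation), -0.14 (glutathione), -0.049 (ribosomal proteins) and -0.31 (straight proximal tubule) without HET replicate 2.

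The other called lists were higher in the libraries labelled HET. They were lymphocytes (15 of 20 members, median 0.60, camera adjusted p = 0.0102), urothelium (12 of 14, 0.26, 0.00717), mesangial and smooth muscle cells (18 of 18, 0.15, 0.0102) and synapse and axon genes (22 of 25, 0.12, 0.0259). In the mesangial list only 5 members were above both WT libraries in both HET libraries. Each of these lists had an adjusted p = 0.806 with an estimated correlation. Over all genes 0 of their members were called, and adjusted over the list alone 0 members of the lymphocyte, urothelium and mesangial lists. Without HET replicate 2 the lymphocyte list was lower (0.0412), and the urothelium (0.156), mesangial (0.289) and synapse (0.122) lists were not called by camera. Without WT replicate 1 urothelium (0.363) and synapse (0.115) were not called either. Without scaling of the TPM, camera did not call lymphocytes (0.586, median 0.76) or synapse genes (0.701, median 0.17). With the filter at 1 read per 1000000 camera did not call lymphocytes (0.258, median 0.23) or synapse genes (0.187, median 0.27). With Y-linked gene level as a covariate camera did not call synapse genes (0.135, median 0.14). Camera did not call lymphocytes (0.223, median 0.53), urothelium (0.703, median 0.076, tested as lower), mesangial cells (0.478, median 0.085) or synapse genes (0.561, median 0.046) with Xist level as a covariate. Among lists still called, the median was 0.17 for urothelium with the filter at 1 read per 1000000, 1.18 for lymphocytes and 0.26 for mesangial cells with Y-linked gene level as a covariate, 0.43 for urothelium and 0.39 for mesangial cells without scaling of the TPM, 0.90 for lymphocytes and 0.51 for synapse genes with limma-voom, 0.28 for synapse genes with a pseudocount of 0.1 and 0.061 for synapse genes with a pseudocount of 1. Median log2 fold changes were 0.072 (synapse genes) without WT replicate 1, 1.26 (lymphocytes) and 0.26 (mesangial cells) without HET replicate 1 and -0.15 (lymphocytes) and 0.15 (synapse genes) without HET replicate 2. The remaining 18 lists had camera adjusted p from 0.111 to 0.793. They were blood cells, medullary osmolyte response, endothelium, kidney and ureter development, hypoxia, unfolded protein response, fatty acid oxidation, skeletal muscle, the renin-angiotensin system, thin limb, adipose tissue, early proximal tubule, cholesterol synthesis, adrenal gland, neighbours of Tshz3, female kidney, circadian clock and sex chromosomes. The female kidney list was tested as lower although its median was 0.11 and its mean 0.013. Adjusted over the list alone, 2 hypoxia genes (Car9 and Egln3, both lower), 2 female kidney genes (Cyp2a4 and Cyp2a5, both lower) and 1 neighbour of Tshz3, Pop4, were called, and 0 in the other uncalled lists.

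Genes near Tshz3 on chromosome 7 were compared with the rest, since a targeted allele is inherited together with the DNA around it. The authors' deposited table holds 8 of 336 genes within 10 Mb of Tshz3, where 1.85 would be there by chance (Fisher's exact test, two-sided, p = 0.000539, adjusted p = 0.00189 over 7 such tests). The adjusted p was 0.00767 within 5 Mb (3 genes) and 0.00189 within 20 Mb (10 genes). These windows are nested, so their tests are not separate support. Fisher's test takes genes as independent, but 1600014C10Rik and D530033B14Rik, counted in every window, overlap each other. All 8 genes within 10 Mb lie on the distal side of Tshz3. Pop4, a ribonuclease P subunit gene 1.53 Mb away (38261996 to 38271423), was at 4.98 ± 0.0786 TPM in WT and 9.15 ± 0.399 TPM in the libraries labelled HET (SD, n = 2). 1600014C10Rik (38183217 to 38197568) was at 73.1 ± 3.25 TPM and 45.0 ± 3.39 TPM (SD, n = 2), and D530033B14Rik overlaps it on the other strand, so their reads cannot be told apart. Fcgrt, the neonatal Fc receptor gene (45092990 to 45103851), was at 273 ± 10.9 TPM and 153 ± 14.3 TPM, and Aspdh at 133 ± 29.1 TPM and 82.2 ± 0.876 TPM (SD, n = 2). Zfp658, Klk1b27 and Mybpc2 are higher in the authors' deposited table (0.98, 0.72 and 0.76). None of these genes passed the limma test over all genes, which called 0 of 426 genes in the window. Among genes that reached the lowest count of the authors' deposited table, 26 in the window had an unadjusted p under 0.05, where 22.1 would by chance (Fisher's exact test, two-sided, p = 0.374, adjusted p = 0.564).

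**Figure D4:**
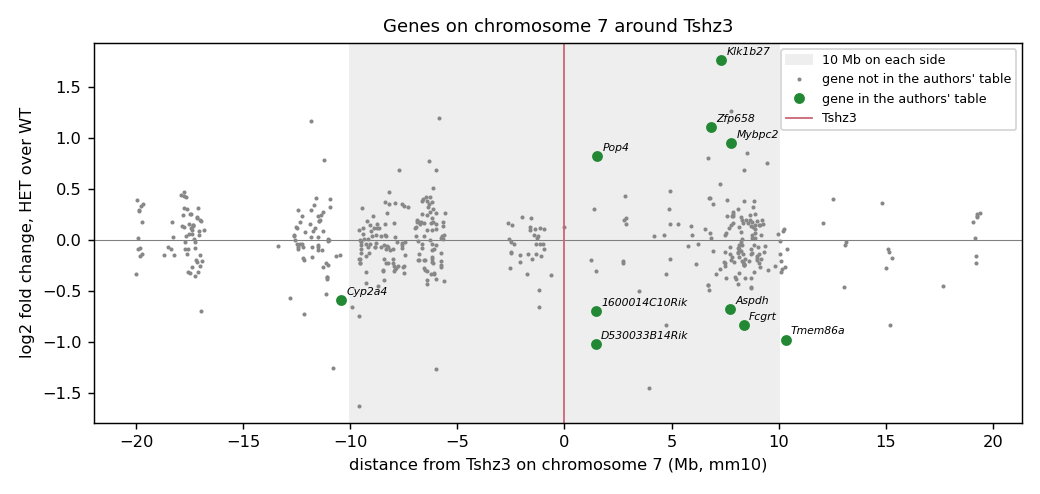
Log2 fold change, HET over WT as labelled (y axis), of genes on chromosome 7 within 20 Mb of Tshz3 against their distance from Tshz3 in Mb (x axis, mm10), with genes of the authors' deposited table in green and 10 Mb on each side shaded. Within the shaded part lie 8 of the authors' genes.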

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

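TPM without scaling, pseudocounts, moderation without the robust option, the Y-linked and Xist covariates, limma-voom for the lists, both splits that mix the genotypes and the counts of calls shared with the authors under every alternative except an adjusted p of 0.05 were chosen after the data had been seen. The 2 called genes were the same genes with other scaling factors, without scaling and with pseudocounts of 0.1 and 1. Limma called 0 genes without a filter (1945 at an unadjusted p under 0.05), 5 at 1 read per 1000000, 1 at an adjusted p of 0.05, 0 with limma-voom (1771), 1 without robust moderation, 32 with the Y-linked and 0 with the Xist covariate (402), and 2 to 76 with 1 library left out, where the lone library of a genotype is assumed to vary like the others. Calls shared with the authors, 2 in all, were 0 without a filter, 5 at 1 read per 1000000, 1 at an adjusted p of 0.05, 0 with limma-voom, 1 without robust moderation, 6 with the Y-linked and 0 with the Xist covariate, and 1 to 7 with 1 library left out. With a replicate block limma called 0 genes, 0 of them shared with the authors, and 1766 had an unadjusted p under 0.05. The numbers were not taken to pair the samples, as there are only 2 pairs; across genes the step from replicate 1 to 2 in WT correlated with that in HET with a Pearson r of 0.123 and a Spearman rho of 0.0799. Over all alternatives the log2 fold change was -3.25 to -2.44 for Npy, 3.13 to 5.07 for Gm8420 and 0.035 to 0.28 for Tshz3, which was never called. Their limma adjusted p was 0.00106 to 0.721 for Npy and 0.000563 to 0.618 for Gm8420. Called lists numbered 0 with an estimated correlation, 0 with fry, 7 with the Xist covariate and 16 to 25 with 1 library left out. Of the 20 lists, 3 were still called with the Xist covariate, fibroblast and matrix genes among them in the other direction, 12 with the Y-linked covariate, and 14, 20, 13 and 14 without WT replicates 1 and 2 and HET replicates 1 and 2, lymphocytes in the other direction in the last. Lists that changed direction had, with the Xist covariate, camera adjusted p of 0.915 (cell cycle), 0.0711 (fibroblast and matrix), 0.703 (urothelium) and 0.691 (collecting duct), and with the Y-linked covariate 0.892 (intercalated cells), 0.603 (collecting duct) and 0.327 (thick ascending limb). With 1 library left out they had 7.82e-11 to 0.933 (distal tubule), 4.18e-18 to 0.0517 (lymphocytes), 5.33e-06 to 0.732 (intercalated cells), 3.81e-06 to 0.595 (collecting duct) and 1.04e-06 to 0.290 (thick ascending limb). Among genes that never passed, Tshz1 was at 0.059 without scaling and 0.11 with the Xist covariate, Tshz2 at -0.19 with that covariate and -0.015 to 0.30 with 1 library left out, Aqp2 at -0.37 and -0.15 with the Y-linked and Xist covariates and -0.38 to 0.42 with 1 library left out, and Umod at -0.00239 with the Y-linked covariate. The cause of these changes was not tested. Parted by replicate number, the libraries gave 2 called genes (Igkv10-96 and Igkv8-27), and parted crosswise 0 by limma (596 at an unadjusted p under 0.05). In windows of 5, 10 and 20 Mb around Tshz3, 0 genes were called by limma. The edgeR quasi-likelihood, exact and likelihood-ratio tests and DESeq2 were not run, as the deposited unit is TPM, although the recovered reads could have served. What depth limits was not tested: the replicates differed beyond counting error over all genes (chi-square per degree of freedom 70.6 in WT and 73.2 in HET), but Tshz3 rested on 104 to 145 reads and Gm8420 on 5 in each WT library.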

Other observations

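All tests of explanations in this part were chosen after the data had been seen. Among lymphocyte genes, Ighm, the heavy chain of IgM, was at 8.38 and 8.98 TPM in WT and 9.54 and 60.6 TPM in HET replicates 1 and 2, and Cd79b at 0.647 and 1.41 TPM and 0.997 and 7.09 TPM; both were picked after their values were seen. Genes of adipose tissue had a median relative to the WT mean of -0.29 and 0.29 in WT and -0.22 and 0.88 in HET. The MHC class II gene H2-Eb1 varied between pools of a genotype, at 5.88 and 36.8 TPM in WT and 71.5 and 26.0 TPM in HET. The first principal component held 46.9% of the variance, with scores of -39.2 and -2.51 in WT and 18.4 and 23.4 in HET. The second held 35.9% and set HET replicate 1 (33.4) apart from HET replicate 2 (-26.0).

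Macrophage and dendritic cell genes were higher in both HET libraries, and more female tissue in these pools cannot be told apart from other causes, as the markers of sex disagree: the male kidney list was lower in HET and Xist was higher, but the female kidney list had 11 of 18 members higher and a median of 0.11 (camera adjusted p = 0.743, tested as lower), with Cyp2a4 and Cyp2a5 lower in HET, and relative to the WT mean it was at 0.25 and -0.16 in HET replicates 1 and 2. Cyp2a4 and Cyp2a5 lie on chromosome 7, at -10.4 and -9.90 Mb from Tshz3. Their fall can thus not be told apart from an effect of the region around the targeted allele. The macrophage list was still called higher with Xist level as a covariate (median 0.35, camera adjusted p = 5.27e-05), which cannot separate sex from genotype in these libraries. If female tissue were the whole cause and acted in proportion to its marker, the step from HET replicate 2 to HET replicate 1, 0.0185 (bootstrap 95% interval -0.101 to 0.186), would be 0.588 by the male kidney list but 0.0335 by Xist, and the step from WT replicate 1 to WT replicate 2, 0.191 (0.0822 to 0.315), would be 0.353 and 0.547. Lymphoid tissue dissected with the kidneys would raise lymphocyte genes, whose median step from WT replicate 2 was -0.171 to HET replicate 1 (-0.352 to -0.0249) and 1.23 to HET replicate 2 (0.765 to 1.72). All intervals in this paragraph cover the spread over the genes of a list between single pools, not the spread between pools. The values thus gave no sign of that source in HET replicate 1, without excluding it, and it stays open in HET replicate 2. A change in macrophages or in MHC class II expression with the genotype remains open as a hypothesis, as do other differences between the pools.

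Genes of male-type kidney were lower in HET than in WT. Fewer male kidneys in the pool of HET replicate 1 may account for part of this but are not established, since the mean log2 level of 4 Y-linked genes differed from that in HET replicate 2 by -1.85 while Xist was at 60.5 and 57.7 TPM in these pools. A change shared by both HET pools cannot be told apart from differences between single pools. Without HET replicate 1 the list was still lower (camera adjusted p = 0.00243), which by the criterion first written would have spoken for a shared change. That criterion was set aside after its result was seen, because the list in HET replicate 2 differed from WT replicate 2 by only -0.0468 and because camera also called 16 and 23 lists when the genotypes were mixed.

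Genes of the authors' table were frequent near Tshz3, and flanking DNA of another strain, carried along with the targeted allele, is a candidate explanation that cannot be told apart from an effect of the allele on its neighbours, as no genotypes were analysed here. It would also be expected to change other genes around the locus. Of 328 genes outside that table within 10 Mb, 18 had an unadjusted p under 0.05 in limma, where 19.9 would by chance (Fisher's exact test, two-sided, p = 0.727, 95% interval of the odds ratio 0.522 to 1.45). Of the authors' 97 genes 96 had such a p, so leaving them out lowers the count where they are frequent. The test thus neither shows nor excludes flanking DNA of another strain. With each of 17591 genes as the centre of a window, 0.0877% of those farther than 20 Mb from Tshz3 had an excess of the authors' genes as strong. Those centres lay on 1 chromosome. Windows of neighbouring genes overlap, so this share is not a chance rate. Reads shared between overlapping genes do not account for the count, since 6 of the 8 genes overlap no other gene of that table. Background elsewhere stays open too, as the segment of chromosome 2 with Cwc22 is known to vary in copy number between mouse strains.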
